A study of Homo sapiens with 6 samples.

How the data were processed

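RNA-seq of 6 MKN45 libraries was compared, 3 labelled with an shRNA against tcons_00001221 and 3 with a control shRNA. Groups and replicate numbers came from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made by Illumina protocols. The authors deposited FPKM per gene and FPKM per transcript in 2 tables, and no counts were used here. The builds hg19 and GRCh37 come from the submitters' processing notes. The aligner, the quantification tool, the annotation version and strandedness are not given in the sources used here.

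Every one of the 11658 genes and 30432 transcripts in the tables had a mean of at least 0.5 FPKM in the group where it was higher, and all were of the protein-coding type, so genes below that level and non-coding genes were not analysed here. Depth is unknown: at a tolerance of 0.1 of a step, 22.3% to 23.5% of low values per library lay at whole multiples of a common step, where 20% do by chance, so whole reads could not be recovered. No pair of libraries held identical values. FPKM divides by a total, so a change in a few abundant genes shifts all others slightly. It also depends on how the tool divides reads between overlapping genes and between transcripts of a gene, which can move a value between libraries without any change in the amount of RNA.

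Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1 (limma-trend). Features with at least 1 FPKM in at least 3 of the 6 libraries were tested, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The filter left 10675 genes and 20890 transcripts. Fold changes are on the log2(FPKM + 1) scale unless group means are given, and signed log2 changes are target minus control. Errors are SDs over 3 libraries or, for log2 changes, moderated SEs. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

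Of 43 gene lists, chosen before the data were examined along with the tests of the report, the rule for named genes and the alternatives not marked as added, 39 had at least 3 tested members, 3 had fewer, and a list of long non-coding RNAs had none in the tables used here. Of their members 784 matched by symbol, 14 by a current symbol through the gene identifier, and 213 were not among the genes analysed here. Lists were tested with camera (inter-gene correlation preset at 0.01) and again with camera with an estimated correlation, and fry was run beside them. Camera compares a list with the other genes. Fry asks whether a list's genes move, on balance, one way. Its adjusted p was 4.97e-05 for the amino acid list and 3.99e-05 for the interferon list. Of other lists that camera called, fry passed NF-kB and inflammatory genes (0.0016), the unfolded protein response (0.0016), fibroblast markers (0.044) and ERK pathway feedback genes (0.047). The rest of those did not pass fry (adjusted p 0.051 to 0.558). Fry also passed lists that camera did not call, all as higher: mitosis (0.044), p53 targets (0.044), apoptosis regulators (0.042) and oxidative stress (0.047). Whole chromosomes passed fry as higher too, such as chromosomes 1 and 11 (adjusted p 0.017 each over the chromosomes), though chromosome 18 did not (0.423). A small rise over most genes can thus pass fry, so these passes do not set the lists apart from other genes.

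The genes named were the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 2 FPKM and groups that did not overlap. To these came up to 4 members of smallest p from each list described, any member past the threshold that went against its list, PTP4A1, WDR5, KAT2A, and the 3 genes of highest mean. Transcripts were named by the same rule, with 5 in each direction. Further list members named for contrast, and genes named with a statement to that effect, were chosen after their values were seen. Some genes that the rule selects are not reported here.

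The fits were tested on simulated data with the real means and spread of the 10675 genes, of which 200 were changed in each of 5 sets. Of the changed genes, 21.6% were recovered at 1.25-fold, 54% at 1.5-fold, 79.2% at 2-fold and 90% at 4-fold, with 4.52% false calls. In the same test on 20890 transcripts, 10.4% were recovered at 2-fold and 32.8% at 4-fold, with 5.69% false calls. Camera called 20 of 20 simulated lists of 25 genes raised by 0.3 (log2) and 1 of 20 unchanged lists at an unadjusted p of 0.05. Genes were drawn independently of each other, so this does not show how camera behaves on lists of correlated genes.

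Alternatives were other pseudocounts (0.1 and 0.01), no filter, a mean of at least 5 FPKM, quantile normalization, rescaling to the same median, limma without the trend, robust limma, the replicate number as a block, other thresholds, and leaving out each library in turn. Leaving out features that range widely within a group, and the locus sums below, were added after seeing the data, as were some tests of the closing section. To see whether changes came from the division of reads between models, FPKM times transcript length (GENCODE 29, which gave a length to 99.4% of transcripts) was summed over all listed transcripts of genes that overlap on a strand, called locus sums. Positions come from the tables. GENCODE 29 is built on another assembly and gave lengths and names only. Intervals of medians are from 2000 bootstrap draws over genes.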

Results

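RNA was sequenced from MKN45, an established human gastric cancer cell line, after transfection with a short hairpin RNA (shRNA) against the transcript tcons_00001221 or with a control shRNA. An shRNA is processed by the cell into a small interfering RNA that lowers the level of the matching transcript. There were 3 libraries with the target shRNA and 3 with the control shRNA, and the single comparison of the design asks what changed in the cells when this transcript was targeted. The tables gave FPKM (fragments per kilobase of transcript, scaled to the mapped total) for 11658 protein-coding genes and 30432 protein-coding transcripts, with positions on GRCh37. The sum of gene FPKM ranged from 186226 to 192101 over the 6 libraries, and mitochondrially encoded genes made up 5.94% to 6.35% of it. The number of reads behind these values is unknown, so no counting error can be given. Gene values correlated at Pearson's r of 0.985 to 0.987 within the control libraries, 0.987 to 0.988 within the target libraries and 0.983 to 0.986 between groups (across genes, which are not independent replicates). Transcript values correlated less, at 0.857 to 0.872 within groups and 0.852 to 0.867 between them. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

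The targeted transcript, tcons_00001221, was not analysed here, because 0 of the 11658 genes and 30432 transcripts carried that identifier. The size of the knockdown is therefore not part of the comparison, and groups are named by their labels.

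With the target shRNA, genes on the lists of the interferon response and of the amino acid starvation response were higher. A smaller set of genes, among them the transcription factor SOX4 and the lipid droplet protein PLIN3, was lower. Of 10675 genes tested, 80 passed an adjusted p of 0.05, with 57 higher and 23 lower. On the scale of log2(FPKM + 1), 9 rose and 4 fell by at least 2-fold, and the median size of the log2 change among the 80 was 0.48. In all 80 genes every library of one group lay above every library of the other. Over all tested genes this held for 23.7%, where chance gives 10% with 3 against 3. The median log2 change of all tested genes was 0.03. Without control replicate 1, 2 or 3 the test called 44, 25 and 35 genes, and without target replicate 1, 2 or 3 it called 30, 24 and 22. With the replicate number as a block it called 10. When values were summed over all listed transcripts of overlapping genes, 37 of the 80 passed in the same direction and 3 changed sign.

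Of the 12 largest rises among genes with a mean of at least 2 FPKM, 6 were genes of the interferon response, which cells switch on when they sense viral or other foreign nucleic acid. OASL, related to the enzymes that sense double-stranded RNA, rose from 2.24 ± 0.204 to 9.16 ± 0.206 FPKM (SD, n = 3 per group), a log2 change of 1.65 with an SE of 0.06 (adjusted p = 0.00039). It lies on chromosome 12 at 121456914 to 121477045, minus strand. ISG15, a ubiquitin-like modifier on chromosome 1 at 936518 to 949921, plus strand, was far more abundant and rose from 61.3 ± 1.05 to 166 ± 11.2 FPKM, a log2 change of 1.42 with an SE of 0.06 (adjusted p = 0.00039). IFIT2, an RNA-binding protein that restrains translation, rose from 1.41 ± 0.195 to 6.01 ± 0.50 FPKM (adjusted p = 0.0019). IFI44 rose from 1.92 to 4.87 FPKM, DDX60 from 2.03 to 4.83 and IFIT3 from 2.76 to 6.20, with adjusted p of 0.012, 0.0025 and 0.012.

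The interferon response list was fixed with 33 genes. MX1, MX2, OAS2, IFI27, IFI44L, RSAD2, CMPK2, XAF1, CXCL10, IFNB1 and IFNL1 were not among the genes analysed here, so whether they rose is unknown. All genes analysed had a mean of at least 0.5 FPKM in their higher group. These members may thus have lain below that level in both groups, target libraries included. Of its 22 tested members 9 were higher, 0 were lower and 13 did not pass. Adjusted over the list alone, 15 were higher. The remaining 3 that rose were DDX58, the cytosolic sensor RIG-I (1.47 ± 0.105 to 3.08 ± 0.185 FPKM), IFIT1 (0.957 ± 0.065 to 2.73 ± 0.362) and ISG20 (2.50 ± 0.072 to 3.91 ± 0.111). By locus sum, 3 of the 9 lost their calls, though their log2 changes were not smaller. They were IFI44 (1.01 to 1.03, adjusted p = 0.205), DDX58 (0.72 to 0.87, 0.308) and ISG20 (0.49 to 0.62, 0.094). The rise was not shared evenly. STAT2, a transcription factor of the interferon pathway, measured 6.64 and 7.34 FPKM (adjusted p = 0.692), and BST2, a membrane protein that holds back viruses, 124 and 127 (0.795) in control and target libraries. The median log2 change of the tested members was 0.36. The list passed camera with an adjusted p of 1.2e-15, and it held with an estimated correlation (adjusted p = 0.015). With only the 9 members of mean at least 5 FPKM the median was 0.20. Most of these genes were low, at under 10 FPKM, and the log2(FPKM + 1) scale understates changes of such genes.

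**Figure D1:**
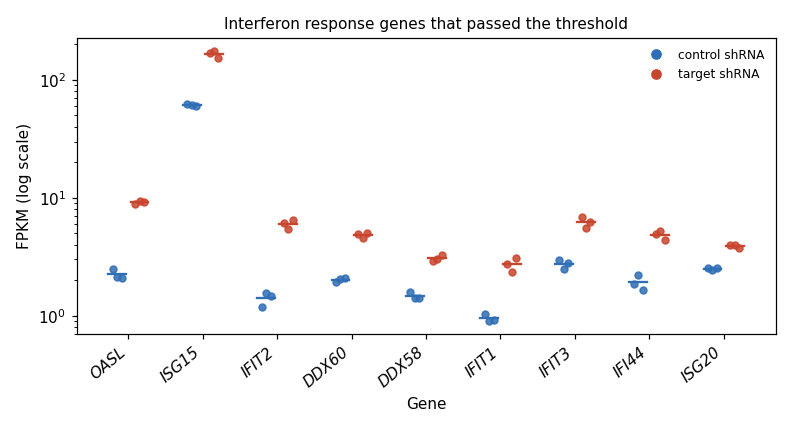
FPKM on a log scale of the 9 interferon response genes that passed the threshold, in the 3 control and 3 target libraries. Points are libraries and bars are group means. Every target library lies above every control library in each gene, with ISG15 at 61.3 and 166 FPKM and OASL at 2.24 and 9.16 FPKM in the means of the groups.

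The list of the amino acid starvation response holds genes of the program that the transcription factor ATF4 runs when amino acids are short. Amino acid levels are not part of these data, so a rise of the list does not show a shortage. Of its 25 tested members 9 were higher, 0 were lower and 16 did not pass. Adjusted over the list alone, 21 were higher. PSAT1, an enzyme of serine synthesis on chromosome 9 at 80912059 to 80945009, plus strand, rose from 38.8 ± 1.77 to 67.5 ± 0.125 FPKM (SD, n = 3 per group), a log2 change of 0.78 with an SE of 0.04 (adjusted p = 0.0019). ASNS, which makes asparagine, rose from 9.23 ± 1.11 to 17.4 ± 0.362 FPKM (adjusted p = 0.016). AARS, the alanine-tRNA ligase, rose from 54.4 ± 0.889 to 76.1 ± 1.04 (adjusted p = 0.0049), and CEBPG, a partner of ATF4, from 6.73 ± 0.087 to 10.7 ± 0.413 (adjusted p = 0.0084). ALDH1L2, SESN2, the cystine transporter SLC7A11, the cysteine-tRNA ligase CARS and NUPR1 made up the other 5, with log2 changes of 0.57, 0.62, 0.63, 0.43 and 0.55. By locus sum, CARS (log2 change 0.43 to 0.57, adjusted p = 0.155) and NUPR1 (0.55 to 0.88, 0.078) lost their calls. In other settings ASNS kept its call in 11 of 16, SLC7A11 in 10 of 15 and SESN2 in 9 of 15. ATF4 itself, which is controlled largely at translation, measured 111 ± 1.96 and 128 ± 1.48 FPKM and did not pass (adjusted p = 0.061). TRIB3 measured 25.5 ± 1.34 and 46.1 ± 15.7 FPKM (adjusted p = 0.243), and 1 of its 3 target libraries, at 28.1, lay near the control values. The list's median log2 change was 0.39, with an adjusted p of 3.7e-18 by camera and of 0.015 with an estimated correlation.

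**Figure D2:**
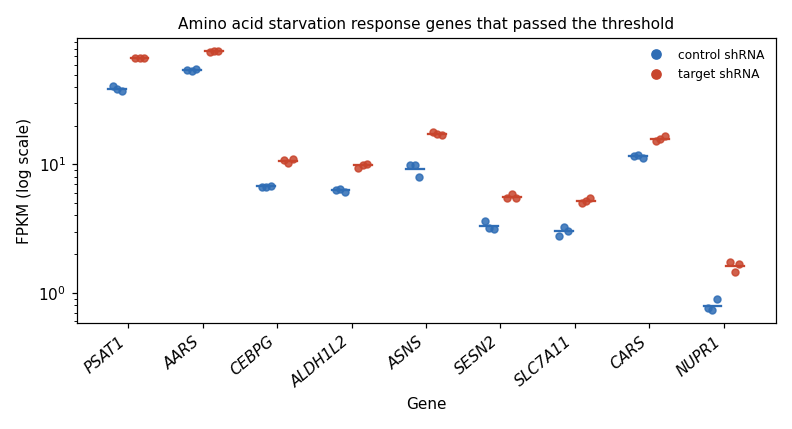
FPKM on a log scale of the 9 amino acid starvation response genes that passed the threshold, in the 3 control and 3 target libraries. Points are libraries and bars are group means. PSAT1 lies at 38.8 and 67.5 FPKM and ASNS at 9.23 and 17.4 FPKM in the means of the control and target groups.

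Outside these lists, the largest rises among genes with a mean of at least 2 FPKM were of ADNP, a zinc finger protein of chromatin (7.90 ± 1.05 to 23.2 ± 0.522 FPKM, adjusted p = 0.0022), ZFP1 (1.57 ± 0.543 to 4.44 ± 0.567, adjusted p = 0.049), SEC61A1, the channel that moves proteins into the endoplasmic reticulum (67.8 ± 11.4 to 136 ± 1.89, adjusted p = 0.021), and FAM129B (71.8 ± 2.25 to 136 ± 3.01, adjusted p = 0.00054). The call of ZFP1 was kept in 3 of 15 other settings (adjusted p 0.020 to 0.216) and lost in its locus sum (log2 change 1.09 to 1.81, adjusted p = 0.149). That of SEC61A1 was kept in 10 of 16 (up to 0.123). Of genes named in advance, PTP4A1, a phosphatase, rose from 54.5 ± 3.35 to 77.3 ± 0.158 FPKM, a log2 change of 0.50 with an SE of 0.05 (adjusted p = 0.018, with the call kept in 10 of 16 other settings). WDR5, a subunit of histone methyltransferase complexes, measured 26.7 ± 0.345 and 28.9 ± 0.285 (adjusted p = 0.239), and KAT2A, a histone acetyltransferase, 6.93 ± 1.34 and 7.27 ± 0.260 (adjusted p = 0.793). The 3 genes of highest mean did not pass: FTH1, a subunit of ferritin, measured 2658 ± 93.1 and 2252 ± 62.3 FPKM (adjusted p = 0.073), GAPDH 2268 ± 138 and 2082 ± 103 (0.366), and TMSB10 2157 ± 81.1 and 1886 ± 138 (0.229).

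The largest fall was that of RP11-529K1.3, a gene model on chromosome 16 at 70333097 to 70406485, plus strand, from 9.54 ± 0.878 to 0.142 ± 0.153 FPKM, a log2 change of -3.21 with an SE of 0.11 (adjusted p = 0.00039). It overlaps DDX19B and DDX19A on the same strand, so reads can be shared between them, and the sum over the 3 genes changed by -0.26 and did not pass (adjusted p = 0.404). DDX19A measured 1.99 and 4.74 FPKM (adjusted p = 0.102) and DDX19B 4.39 and 5.01 (0.524). PLIN3, a protein of lipid droplets on chromosome 19 at 4838353 to 4867780, minus strand, fell from 48.4 ± 1.83 to 23.0 ± 1.65 FPKM, a log2 change of -1.04 with an SE of 0.06 (adjusted p = 0.0022). PCDH1, a protocadherin of cell contacts, fell from 5.43 ± 0.477 to 2.14 ± 0.662 FPKM, and FAM102A from 7.17 ± 0.790 to 3.05 ± 0.269. The call of PCDH1 was kept in 5 of 15 other settings (adjusted p 0.015 to 0.211) and lost in its locus sum (log2 change -1.05 to -1.61, adjusted p = 0.157). ARHGEF18 fell from 20.2 to 11.6 FPKM and COPS7A, a subunit of the COP9 signalosome, from 11.5 to 6.43. The carboxypeptidase CPA4 fell from 22.3 to 14.8 FPKM, METRN from 6.11 to 3.83, and SOX4 from 33.7 to 23.9. The inositol transporter SLC5A3 fell from 54.9 to 39.3 FPKM, PMEPA1 from 19.96 to 14.4 and ELF2 from 3.27 to 2.15. Adjusted p over these 12 falls ranged from 0.00039 to 0.049. METRN and ELF2 kept their calls in 9 and 8 of 15 other settings and PMEPA1 in 8 of 16, with adjusted p up to 0.211, 0.211 and 0.160, while ARHGEF18, COPS7A, SOX4 and SLC5A3 kept theirs in 10 of 16. By locus sum METRN (log2 change -0.56 to -0.74, adjusted p = 0.106) and PMEPA1 (-0.44 to -0.47, 0.078) lost their calls.

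**Figure D3:**
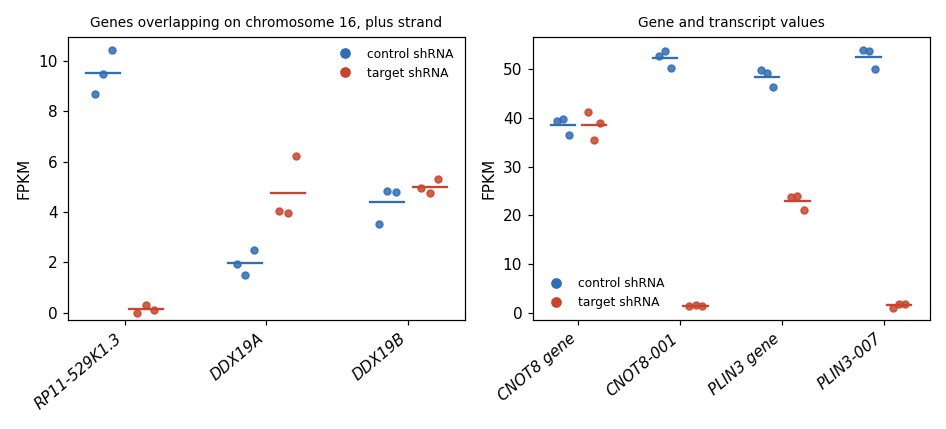
FPKM of RP11-529K1.3 and the genes DDX19A and DDX19B that overlap it (left), and of CNOT8 and PLIN3 as genes and as single transcripts (right), in 3 control and 3 target libraries. Points are libraries and bars are group means. RP11-529K1.3 lies at 9.54 and 0.142 FPKM while DDX19A lies at 1.99 and 4.74. CNOT8-001 lies at 52.2 and 1.51 while the CNOT8 gene lies at 38.6 and 38.5. Gene and transcript FPKM are not on the same scale, so a transcript can lie above its gene.

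Of the 39 lists that could be tested, 14 passed camera with the preset correlation, 4 higher and 10 lower, but only the interferon and amino acid lists held with an estimated correlation. For the other 12 that adjusted p was between 0.203 and 0.538. The estimate lay below the preset 0.01 for NF-kB (-0.012), unfolded protein response (-0.025), fibroblast (-0.068) and ERK genes (-0.031). It also lay below it for glycolysis (0.0017), invasion and motility (-0.030) and autophagy and lysosome genes (-0.0078). A higher correlation therefore does not account for the loss of these calls. For the amino acid list the estimate (-0.0018) was also below the preset, yet its unadjusted camera p went from 9.6e-20 to 0.00053. Camera with a preset and with an estimated correlation thus differ in more than the correlation. A lost call does not by itself show that a list's genes are correlated. For the rest of the 12 the estimate was above 0.01, up to 0.706 for ribosomal proteins. Under quantile normalization 10 lists passed, 5 higher and 5 lower: ribosomal proteins (adjusted p = 0.106), glycolysis (0.571), invasion and motility (0.397), TGF-beta and BMP targets (0.053) and autophagy and lysosome genes (0.064) lost their calls. The list of NF-kB and inflammatory genes was higher (median log2 change 0.17, adjusted p = 0.0064, and 0.203 with an estimated correlation). Of its 14 tested members only the cytokine IL6 passed, rising from 1.38 ± 0.063 to 2.16 ± 0.069 FPKM, and 8 were higher and 1 lower adjusted over the list alone. The call of IL6 was kept in 7 of 15 other settings (adjusted p 0.026 to 0.211) and lost in its locus sum (log2 change 0.41 to 0.67, adjusted p = 0.376). TNFAIP3 measured 12.5 and 14.8 FPKM (adjusted p = 0.141) and IL1A 10.6 and 14.5 (0.145). The unfolded protein response list was higher (median 0.11, adjusted p = 0.011, and 0.203 with an estimated correlation). It shares CHAC1 and TRIB3 with the amino acid list, so its call is not independent of that list's. Of 23 tested members only DDIT3, the stress factor CHOP, passed, rising from 5.98 ± 0.379 to 9.59 ± 0.610 FPKM, and 5 were higher and 1 lower adjusted over the list alone. The DDIT3 call was kept in 9 of 16 other settings (adjusted p 0.012 to 0.178) and lost in its locus sum, which changed by 0.41 (0.371). DDIT3 overlaps MARS on the opposite strand. Strandedness is not given, so reads may be shared between them, and locus sums, which join genes of the same strand, do not test this. The chaperone HSPA5 measured 219 and 231 FPKM (adjusted p = 0.290) and ATF3 3.95 and 2.18 (0.064).

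The mesenchymal genes had a median log2 change of -0.12 (adjusted p = 0.0014, and 0.203 with an estimated correlation). Of 15 tested members 1 was lower and 14 did not pass, and 1 was higher and 3 were lower adjusted over the list alone. The cadherin CDH2 measured 6.66 and 5.16 FPKM (adjusted p = 0.082) and the collagen COL5A1 260 and 221 (0.094). Of 19 tested targets of TGF-beta and BMP 2 were lower, among them PMEPA1, which restrains SMAD signalling (median -0.04, adjusted p = 0.026, and 0.249 with an estimated correlation), and 0 were higher and 2 lower adjusted over the list alone. Cytosolic ribosomal proteins had a median of -0.04 and 0 of 50 passed, also over the list alone (adjusted p = 2.8e-05, and 0.538 with an estimated correlation). Invasion and motility genes passed camera as lower (median -0.03, adjusted p = 0.044, and 0.203 with an estimated correlation), but the 2 of 25 that passed singly, PTP4A1 and the integrin ITGA6, rose. ITGA6 went from 7.64 ± 0.865 to 12.7 ± 0.233 FPKM, with its call kept in 10 of 16 other settings and lost in its locus sum (log2 change 0.67 to 0.74, adjusted p = 0.052). Over that list alone 3 were higher and 3 lower.

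The other 6 lower lists had 0 members past the threshold over all genes. They were cholesterol synthesis (median log2 change -0.06, adjusted p = 0.015), fibroblast markers (-0.10, 0.017), ERK pathway feedback genes (-0.02, 0.022), YAP and TEAD targets (-0.01, 0.027), glycolysis (-0.01, 0.030) and autophagy and lysosome genes (-0.04, 0.048). With an estimated correlation the adjusted p of these 6 were 0.225, 0.203, 0.203, 0.499, 0.203 and 0.203. Adjusted over each list alone, 2 cholesterol synthesis genes were higher and 2 lower, 3 YAP and TEAD targets, 1 glycolysis gene and 2 autophagy and lysosome genes were lower, and 0 of the fibroblast and ERK lists passed. PKM, a glycolytic kinase, measured 233 and 185 FPKM (adjusted p = 0.085), GABARAPL1, of the autophagosome, 11.2 and 3.91 (0.067), and CYR61, a YAP target, 45.8 and 37.5 (0.112).

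**Figure D4:**
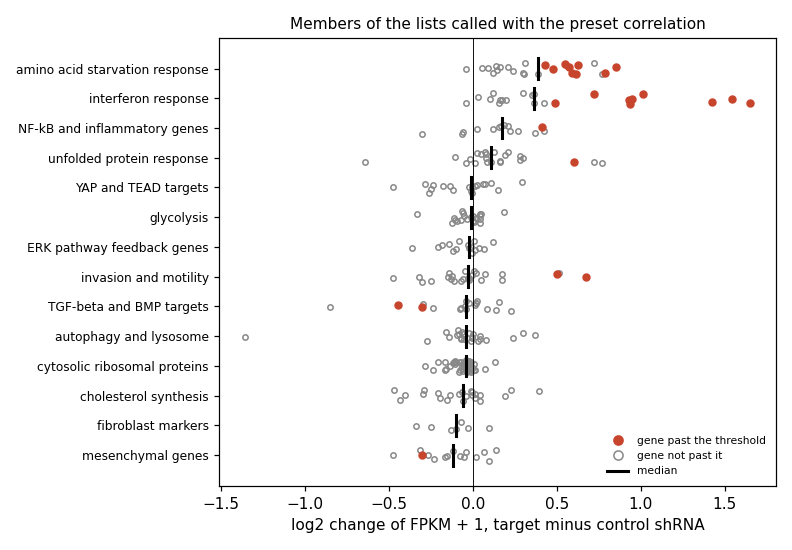
Log2 change of FPKM + 1, target minus control shRNA, of the tested members of the 14 lists called with the preset correlation. Filled points are genes past the threshold, open points are the rest, and black bars are list medians. The amino acid and interferon lists have medians of 0.39 and 0.36, and the medians of the 10 lower lists lie between -0.12 and -0.01.

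The remaining 25 tested lists were not called by camera (adjusted p 0.055 to 0.756, and 0.203 to 0.877 with an estimated correlation). Of these, mitochondrially encoded genes passed as higher under quantile normalization (adjusted p = 1.2e-06) and not under median rescaling (0.297), and DNA replication passed as lower under median rescaling (0.021). They covered DNA replication, mitosis, histone genes, MYC targets, p53 targets, apoptosis regulators, the proteasome, heat shock proteins, hypoxia, oxidative stress, oxidative phosphorylation, mitochondrially encoded genes, fatty acid synthesis, metallothioneins, immediate early genes, Wnt targets, the Notch pathway, growth factors and their receptors, chromatin modifiers, small RNA processing, antigen presentation, epithelial junctions, cancer germline antigens, and gastric and intestinal markers. Among their members SESN2, the apoptosis regulator PMAIP1 (4.97 ± 0.078 to 7.22 ± 0.340 FPKM) and SLC7A11 rose, and TKT, of the pentose phosphate pathway, fell from 70.4 ± 1.58 to 57.7 ± 1.36 FPKM. The calls of PMAIP1 and TKT were kept in 9 and 8 of 16 other settings (adjusted p up to 0.170 and 0.181) and lost in their locus sums (0.120 and 0.161). Their log2 changes went from 0.46 to 0.49 and from -0.28 to -0.29 by locus sum. Of the 13 tested genes of small RNA processing, which carry an shRNA to its target, 0 passed, with a median log2 change of -0.01 and an adjusted p of 0.456. DICER1 measured 4.62 and 4.17 FPKM (adjusted p = 0.468). Of 35 chromatin modifiers 0 passed. The mean and the median of a list differed in sign for heat shock proteins, histone genes and Wnt targets. Endothelial, neuronal and leukocyte markers had 1, 2 and 2 tested members, too few for a list test, and 0 of these 5 passed.

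Among 20890 transcripts tested, 60 passed, 31 higher and 29 lower, and 54 of them by at least 2-fold. Most of these changes lay within genes that changed little: the median size of the log2 change was 1.96 for the transcripts and 0.17 for their genes, and of 59 whose gene was tested 14 had a gene called in the same direction. CNOT8-001, a transcript of a subunit of the CCR4-NOT deadenylase, fell from 52.2 ± 1.83 to 1.51 ± 0.129 FPKM (adjusted p = 0.00023). It lies on chromosome 5 at 154238106 to 154256353, plus strand. The CNOT8 gene measured 38.6 and 38.5 FPKM in control and target libraries. Gene and transcript FPKM are not on the same scale, so a transcript can lie above its gene. Their totals per library were 186226 to 192101 for genes and 288294 to 300121 for transcripts. PLIN3-007 fell from 52.6 ± 2.26 to 1.60 ± 0.429 FPKM, CDIP1-002 from 16.5 ± 0.564 to 0.172 ± 0.157, RP11-529K1.3-003 from 11.7 ± 1.08 to 0.117 ± 0.202 and FXR1-007 from 8.80 ± 0.753 to 0.069 ± 0.052. TCP1-004 was listed at 0 in each control library and at 27.2, 29.5 and 44.6 FPKM in the target libraries, and GIT1-003 at 0 against 6.63, 7.67 and 9.01. PRCC-004 rose from 0.092 ± 0.060 to 19.3 ± 2.15 FPKM, PDE4D-020 from 0.014 ± 0.014 to 13.6 ± 3.43 and KIAA1033-201 from 0.054 ± 0.084 to 10.8 ± 1.2. A 0 here can be an estimate that gave all reads to another transcript of the gene. Within a group, 35.3% of tested transcripts ranged over more than 1 on the log2 scale, against 2.82% of genes. Without control replicate 2 or 3 the test called 32 and 28 transcripts, and without target replicate 1, 2 or 3 it called 17, 13 and 24. The balance moved too, from 38 higher and 6 lower without control replicate 1 to 1 higher and 12 lower without target replicate 2. With the replicate number as a block limma called 0, where 1264 had an unadjusted p under 0.05, and other splits of the 6 libraries into 3 and 3 gave up to 48 calls.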

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

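The interferon and amino acid lists kept their direction and their camera call under every alternative run, with medians of 0.34 to 0.43 (interferon) and 0.34 to 0.42 (amino acid) when a library was left out. The interferon median was 0.20 with a mean of at least 5 FPKM, which left 9 members, and 0.54 with a pseudocount of 0.01. Under the same settings the amino acid median was 0.31, with 18 members, and 0.45. The count of 80 genes became 52 with a mean of at least 5 FPKM, 194 at an adjusted p of 0.1, 13 with a 2-fold limit, and 45 with locus sums, an alternative chosen after seeing the data, in another unit and over 10849 tested loci. Of the 80 genes, 37 passed in the same direction by locus sum and 3 changed sign. Leaving out a library gave 22 to 44 genes: 44, 25 and 35 without control replicate 1, 2 or 3, and 30, 24 and 22 without target replicate 1, 2 or 3, of which at least 16 were among the 80. Fewer libraries lower the power of each of these fits. The count of 60 transcripts became 39 with a pseudocount of 0.1, 15 with 0.01 and 18 with a mean of at least 5 FPKM. It was 44, 32 and 28 without control replicate 1, 2 or 3 and 17, 13 and 24 without target replicate 1, 2 or 3, and higher calls outnumbered lower ones without each control library and the reverse without each target library. Without features that range over more than 1 log2 within a group, also chosen after seeing the data, 96 genes and 146 transcripts passed, and such a filter lowers the estimated spread by its construction. The 14 lists became 2 with an estimated correlation, 9 with a mean of at least 5 FPKM, 10 (5 higher and 5 lower) under quantile normalization, and 9 to 16 without a library, with 9 without control replicate 3. The cause of these moves was not tested where none is given. Calls were 71.3% higher, and 62.2% to 65.2% higher under the 2 rescalings. Of 46 genes and transcripts that the rule for named genes selects and that passed, 0 changed sign under an alternative, locus sums of genes included. All 46 had groups that did not overlap, so only the rescalings and the locus sums could have reversed their sign. Of 139 selected that did not pass, 12 changed sign. Among these 12, GAPDH went from -0.12 to 0.037 under quantile normalization. With locus sums CASP9 went from 0.42 to -0.55, NDRG1 from -0.18 to 0.11, SMAD7 from -0.30 to 0.13 and KAT2A from 0.07 to -0.47, the last in a locus shared with RAB5C and CTD-2132N18.3. With the replicate number as a block, 10 genes and 0 transcripts passed. The numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.01, 0.02 and 0.07 across genes, and not every library correlated best with its own number. The block changed no list call among the 14 and added 1. Alternatives for tcons_00001221 were not run, and unknown depth leaves counting error out of every value.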

Other observations

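Tests chosen only after the result was seen were those of the synthetase genes, the hairpin, stress of the endoplasmic reticulum, the culture, RP11-529K1.3 alone and the other falls. The locus sums, which further tests below use, were also added after the data were seen. Genes in the next paragraph were chosen after their values were seen.

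Aminoacyl-tRNA synthetases load amino acids onto tRNAs, in the cytosol by one set of enzymes and in mitochondria mostly by another. Of 20 synthetase genes counted as cytosolic, 18 were higher with the target shRNA and 6 passed (AARS, CARS, EPRS, GARS, IARS and MARS). Of 17 counted as mitochondrial 11 were higher (median log2 change 0.08) and 0 passed. Each gene was counted in a single set. The mitochondrial set holds no separate counterpart of GARS, KARS or QARS, so these sets may not fully separate the compartments. XPOT, which exports tRNAs from the nucleus, rose from 30.8 to 40.6 FPKM. By locus sum only AARS and IARS passed. GARS went from 0.34 to 0.18 (adjusted p = 0.767), MARS from 0.60 to 0.41 (0.497), CARS from 0.43 to 0.57 (0.155) and EPRS from 0.30 to 0.31 (0.069). MARS overlaps DDIT3 on the opposite strand, and reads may be shared between them, as strandedness is not given. Mean log2 changes of the cytosolic and mitochondrial sets were 0.22 ± 0.18 and 0.02 ± 0.13 (SD over genes), a difference of 0.20 (permutation p = 0.00037, 100000 permutations, two-sided). The amino acid list holds 3 of the 20, and without them the difference was 0.16 (permutation p = 0.0026). With locus sums of all 20 it was 0.18 (permutation p = 0.005). That the rise covers the cytosolic set and not the mitochondrial one stays a hypothesis: it was prompted by the genes it was tested on, which are not independent, so these p-values do not decide it.

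Interferon response genes were higher with the target shRNA. Division of reads between listed transcripts of a gene is argued against. For the 9 that passed, the median log2 change of locus sums was 1.201 (95% bootstrap interval 0.87 to 1.85) against 0.95 in the gene table. Of the 9, 6 were still past the threshold, and over all 22 tested members the median was 0.45 against 0.36. Each of the 9 loci held 1 gene, so a move between genes could not show. IFIT2 and DDX60 had 1 listed transcript, so their sums could not lose the rise. The unit of the sums enlarges changes of low genes, with IFIT2 at 1.85 by sum against 1.54, so the larger medians are partly a matter of scale. A difference in scaling is argued against as well, since the list's median was 0.33 under both rescalings against 0.36. A response to the delivered hairpin rather than to loss of the target stays open and cannot be told apart from it: the labels give 1 group with a hairpin against the target. Double-stranded RNA from transfection could raise RIG-I-type sensors and their targets, which makes a second hairpin the test to run.

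Amino acid starvation genes were higher with the target shRNA. A general stress of the endoplasmic reticulum would raise its chaperones, but the median log2 change of 12 chaperones and folding enzymes was 0.064 (95% bootstrap interval -0.002 to 0.145), below the bound of 50% of the list's 0.39, and 0 of them passed. These 12 are part of the unfolded protein response list, picked after the result was seen. That whole list was higher by camera (median 0.11, adjusted p = 0.011, and 0.203 with an estimated correlation), and its member DDIT3 passed. It shares CHAC1 and TRIB3 with the amino acid list. Locus sums of the 9 that passed had a median of 0.71 (0.57 to 0.88) against 0.59. This argues against division of reads between listed transcripts of a gene, though the unit of the sums enlarges changes of low genes. Each of the 9 loci held 1 gene, so a move between genes could not show. Medium or cell density that differed between the groups at harvest stays open, since 0 libraries have labels that give either, and it cannot be told apart from an effect of the hairpin.

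Changes of at least 2-fold among the called genes could come from reads moved between gene or isoform models. For RP11-529K1.3 the locus sum over DDX19A, DDX19B and itself changed by -0.26 (95% interval -0.47 to -0.05) against -3.21 in the gene table, which is what such a move predicts. For the other 3 falls (PLIN3, PCDH1, FAM102A) the median of the sums was -1.40 (-1.61 to -1.07) against -1.04. For 5 rises outside the interferon list (ADNP, SEC61A1, ZFP1, ARMCX5, CCL5) it was 1.41 (1.03 to 2.33) against 1.09. With so few genes these intervals span no more than the lowest and highest gene. The sums argue against a move among listed transcripts of a gene, though their unit enlarges changes of low genes. Each of these loci held 1 gene, so a move between genes could not show. Over all 4 falls the median was -1.23 (-1.61 to -0.26), which decides nothing. Reads given to transcripts not listed stay open, and AHNAK shows how far a value can jump between replicates, at 165, 6.78 and 7.13 FPKM in the control and 6.38, 152 and 165 in the target libraries.

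Values that fall into 3 low and 3 high libraries with a gap of at least 1 log2 did so along the real groups for 6 genes (ADNP, IFIT2, ARMCX5, OASL, ISG15 and RP11-529K1.3), against a mean of 2.33 and a highest of 4 for the other 9 splits of the libraries. For transcripts these numbers were 97, 80.3 and 93, so that switches of transcripts along the groups were little more frequent than along other splits. The 10 splits of 3 against 3 are too few for a share under 0.05. The real groups gave 80 genes, 60 transcripts and 14 lists, and the highest of the other splits gave 11, 48 and 6.

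The hypothesis that changed genes lie on a gained or lost part of a chromosome was not borne out for whole chromosomes. Over 24 chromosomes, the mitochondrial one included and Y left out, the largest median log2 change was 0.0504, below the bound of 0.2.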
